A study of Homo sapiens with 4 samples.

How the data were processed

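Gene expression was measured in 2 human cell lines, ES2 and H4, each given either the GLI inhibitor GANT61 or its solvent DMSO, with 1 Illumina HumanHT-12 V4 BeadChip array per line and treatment and so 4 arrays in all. Per the labels, the arrays were made after 48 h with GANT61 at 20 µM; the protocol also names an earlier time, which was not analysed here. Per the labels' protocols, total RNA was amplified to biotin-labelled cRNA, hybridized to the BeadChip and read on a BeadArray Reader. The array software and its settings are not given in the sources used here. Each sample was assigned to its line and treatment from its title.

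The authors' deposited value table holds 1 intensity per probe and array on a linear scale for 47229 probes. No value was at or below 0, the smallest values were 35.7 on the ES2 arrays and 52.5 to 53.7 on the H4 arrays, and the medians were 75.1 on each ES2 array and 111.3 on each H4 array. The sorted values of the 2 arrays of a line differed by a median of 0.00457% in ES2 and 0.0103% in H4, against 30.2% between the DMSO arrays of the lines. The values thus carry a quantile normalization made separately within each line, without background subtraction and without a common scale for the lines. A second deposited table holds signals that were not normalized and, per the file headers, a detection p-value for each probe and array. Its 4 signal columns name the line and a number but no treatment, so they were not used, and no match to a treatment was made from their values. Its detection p-values were used without saying which of a line's arrays they belong to, as the number of arrays of a line, 0 to 2, on which a probe was detected at p under 0.01. Its gene column named the probes.

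The design written before the data were examined planned background correction and normalization of the signals that were not normalized. Because neither the labels nor the file headers match those columns to a treatment, the authors' normalized intensity was used in their place. It was background-corrected with normexp (saddle-point fit, offset 16), quantile-normalized over the 4 arrays and taken to log2. All computation was done in R 4.3.3 with limma 3.58.1. A background offset pulls the ratios of dim probes toward 0, and quantile normalization removes any change that all genes share.

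Probe names were brought to current symbols through the RefSeq gene table of GRCh38.p14, used only for names. Of the probes, 27035 carried a current symbol, 4626 a synonym of 1 current symbol, 3485 a gene number and 9 a former symbol named by hand. The file's name was kept for 8750 probes, 3270 had no name, and 54 whose symbol had become a calendar date were left unnamed. A gene was represented by its brightest probe, the one with the highest mean log2 signal over the 4 arrays, which gave 30562 genes. The mean of the detected probes served as an alternative. Among genes with 2 or more probes detected on both arrays of a line, the ratios of the 2 brightest probes correlated across genes with Pearson r = 0.426 in ES2 (2545 genes) and 0.830 in H4 (1993 genes), and their spread was an SD of 0.143 and 0.222 on the log2 scale.

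At p under 0.01, 32.6% and 33.4% of the probes were detected on the ES2 arrays and 27.3% and 30.6% on the H4 arrays. Both arrays of a line detected 14660 probes in ES2 and 12107 in H4. A gene entered the comparison within a line when it was detected on at least 1 of the line's arrays. For a gene detected on 1 array, the ratio is given as a bound, with the dimmer array held at no less than the lowest normalized signal among genes detected on both arrays, and the brighter array was taken to be the one that detected it. The number of arrays limits the precision of every value.

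With 1 array per line and treatment, no comparison within a line has a replicate, a standard error or a p-value. These are described by log2 ratios of GANT61 over DMSO, by counts of genes at least 2-fold different and by gene lists. A list's median log2 ratio was set among the medians of 10000 random lists of the same size matched on signal in 20 bins, and it is said to stand apart when it lay beyond the lowest or the highest 2.5% of them. List medians and counts take the ratio of a gene detected on 1 array as it is, and medians and counts with such genes at their bound, or at 0 where the bound is below 1-fold, are given where they differ most. This describes these arrays. It does not test the treatment. The difference between the lines has no test either.

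The response shared by the lines was fitted with limma (lmFit and eBayes with a trend, cell line as a block) to the 10229 genes detected on at least 1 array of each line. The 2 lines served as the replicates of the treatment, which leaves 1 residual degree of freedom, and adjusted p-values are Benjamini-Hochberg. Gene lists were tested in the same fit with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Nothing in the labels says how cultures were drawn, so limma's p-values for genes measure only the spread between these 2 lines. That spread is shrunken toward that of all genes, with 30.4 prior degrees of freedom. At the preset correlation, camera's p-values measure a list against the spread among genes, not a spread between cultures.

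The tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the Hedgehog pathway, GLI targets, autophagy, lysosome, integrated stress response, endoplasmic reticulum chaperones, DNA replication, mitosis, apoptosis, p53 targets, cholesterol synthesis, fatty acid synthesis, NRF2 targets, heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, interferon, NF-kB and inflammation, matrix and TGF-beta, histones, metallothioneins, WNT and Notch, and markers of Müllerian epithelium, glial and neural cells, mesenchymal cells and blood cells. Named genes were, for each line, the 8 highest and 8 lowest ratios among genes detected on both arrays and the 3 largest bounds in each direction, then the 8 highest and 8 lowest by the smaller ratio of the lines among genes detected on all 4 arrays with the same sign, up to 4 detected members of each list with the largest mean size of ratio, and a fixed set of Hedgehog, autophagy and stress genes. Some genes that this rule takes are not reported here.

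The functions were tested on simulated data made from the DMSO arrays, with the spread of each line's own ratios and a set of genes changed alike in both lines. The shared fit over 10222 genes recovered 59.7% of 67 genes changed by 1 on the log2 scale, 98.5% of 67 changed by 2 and 100% of 66 changed by 3, and called 4 of 9983 unchanged genes. Recovered sizes were compressed: the median ratio of the genes changed by 1 was 0.77 in ES2 and 0.94 in H4. With nothing changed, 5 of 55 list medians stood apart, camera called 0 of 27 lists and the shared fit called 0 genes. The simulated noise was independent between genes, so genes of a list that move together were not covered. No gene was changed in only 1 line. The counts of unchanged genes called thus do not show how often the fit calls a gene that differs mainly in 1 line. Alternatives to the background correction, offset, normalization, probe rule, detection filter, fold threshold, matching of random lists, fitted model and camera settings were chosen before the data were examined, and their effect is given in the closing section. Figures were drawn with matplotlib.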

Results

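ES2 is an established line from an ovarian tumour, commonly described as ovarian clear cell carcinoma. H4 is an established line commonly described as a neuroglioma, although the labels give both lines the same ovarian source. GANT61 is a small molecule that blocks DNA binding by GLI1 and GLI2, the transcription factors at the end of the Hedgehog pathway. The series title states the question, which is whether blocking Hedgehog signalling slows the growth of cancer cells through autophagy. Each line had 1 array from cells given DMSO and 1 from cells given 20 µM GANT61 for 48 h, so ratios within a line have no replicate check, and all are on a background-corrected, quantile-normalized log2 scale. Detection covered 12213 genes in ES2 and 11546 in H4 on at least 1 array.

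Marker genes gave a mixed picture of the lines. Among 22 Müllerian and epithelial markers, ES2 had 4 detected on both arrays (ARID1A, KRT18, KRT7 and KRT8), and so did H4 (ARID1A, KRT18, MUC1 and SLPI). Among 26 glial and neural markers, 7 were detected on both ES2 arrays and 4 on both H4 arrays, the latter being NCAM1, OLIG2, SLC1A3 and TUBB3. Mesenchymal markers were detected more widely, with 7 of 15 in ES2 and 9 of 15 in H4, and VIM, the intermediate filament of mesenchymal cells, lay at the 99.2 percentile of all genes or above on every array. CD68 was the single blood cell marker of 15 that either line detected on both of its arrays.

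H4 cells differed widely between GANT61 and DMSO. Of 11546 genes, 470 were at least 2-fold higher with GANT61 and 405 at least 2-fold lower, together 7.58%. The counts were 329 and 240 without background correction and 256 and 181 on the authors' scale. Of the 470 and 405, 347 and 284 were detected on both arrays. The highest ratios belonged to PSG4, a pregnancy-specific glycoprotein (17.0-fold higher), the WNT antagonist DKK1 (14.6-fold), the activin-binding protein FST (10.9-fold), the matricellular protein CCN1 (10.5-fold), the stress cytokine GDF15 (9.94-fold), SPRY2, an inhibitor of receptor tyrosine kinase signalling (9.53-fold), the cytokine IL24 (9.48-fold) and the lysosome-associated glycoprotein GPNMB (9.23-fold). The lowest were KIF20A, a kinesin of cytokinesis (9.44-fold lower), the zinc finger gene ZSCAN31 (log2 ratio -3.00), the thyroid hormone deiodinase DIO2 (7.51-fold), the CDK4 and CDK6 inhibitor CDKN2C (7.09-fold), LXN (7.02-fold), NREP (6.15-fold), the mitotic spindle protein DLGAP5 (6.10-fold) and the protocadherin PCDH18 (5.14-fold). Some genes were detected on 1 H4 array. The hyaluronan-binding protein CEMIP was at least 10.4-fold higher, the Y RNA RNY4 at least 9.99-fold and the carbonic anhydrase CA9 at least 6.98-fold, whereas the adhesion molecule VCAM1 was at least 7.89-fold lower, the tryptophan-degrading enzyme IDO1 at least 5.25-fold and the glycogenin GYG2 at least 4.33-fold. The VCAM1 bound rests on 1 probe, since a probe detected on both H4 arrays had a log2 ratio of -0.37 and another -0.99, and the other PSG4 probes had 2.48 and 2.39 against 4.09 for the probe used. Second probes went the same way for 137 of the 138 genes at least 2-fold different that had 2 probes detected on both H4 arrays.

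ES2 cells differed far less. Of 12213 genes, 5 were at least 2-fold higher with GANT61 and 4 at least 2-fold lower, together 0.0737%, of which 3 and 2 were detected on both arrays. Those 5 genes were the matrix metalloproteinase MMP3 (2.18-fold higher), ACAT2, an enzyme of the mevalonate pathway (2.10-fold), the 5S ribosomal RNA gene RNA5S9 (2.01-fold), the fucosyltransferase FUT8 (2.29-fold lower) and the immediate early transcription factor EGR1 (2.07-fold lower). Next came QPRT (1.96-fold higher), the aldolase ALDOC (1.91-fold), IL24 (1.79-fold), LOC730994 (1.78-fold) and the heat shock protein HSPA1B (1.70-fold). On the lower side stood the amino acid transporter SLC7A5 (1.96-fold lower), the lipogenic transcription factor SREBF1 (1.70-fold), ZNF777 (1.69-fold), the laminin chain LAMA5 (1.68-fold), PPP1R15A, which recruits the phosphatase of eIF2α (1.66-fold), and BAG6 (1.66-fold). Bounds for genes detected on 1 ES2 array were small, at least 1.33-fold higher for SCG5, 1.30-fold for MYL5 and 1.28-fold for ATMIN, and at least 1.42-fold lower for FLNA, 1.33-fold for KLC2 and 1.32-fold for ZNF768. The counts at 2-fold rest on few genes and were 1 in each direction without background correction. Near-identical sequence copies can share signal on a probe, which applies to the PSG genes, HSPA1A and HSPA1B, the metallothioneins, the histones and the small RNAs named here.

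**Figure D1:**
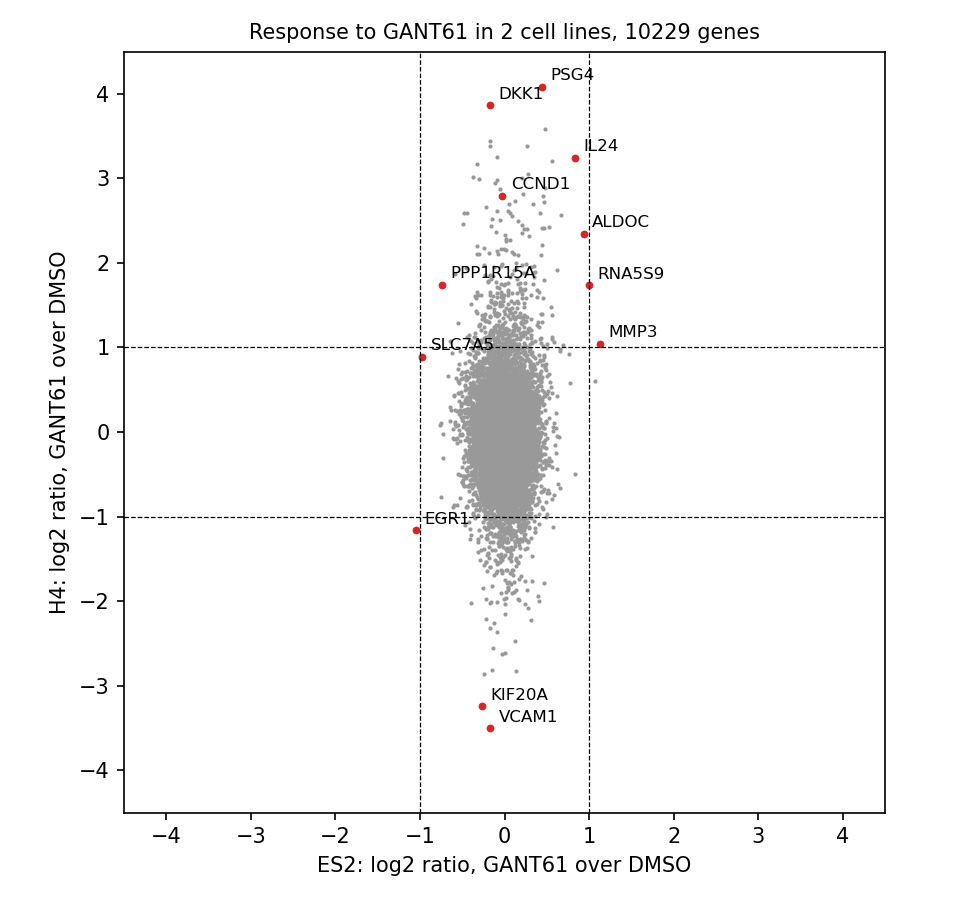
Log2 ratio of GANT61 over DMSO in ES2 (x axis) against that in H4 (y axis), 1 point per gene for the 10229 genes detected on at least 1 array of each line, with dashed lines at a 2-fold difference and 12 genes named in red. The points spread along the H4 axis, and EGR1, MMP3 and RNA5S9 lie at least 2-fold from 0 the same way in both lines.

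The direct question of the series concerns the Hedgehog pathway, most of whose genes were near or below detection. PTCH1, the receptor and a target of GLI, was detected on no array, nor were SUFU, the inhibitor of GLI, and MYCN. GLI1 was detected on no ES2 array and on 1 H4 array, where the dimmer array's floor left no fold to give. GLI2 was 1.27-fold lower with GANT61 in ES2, the ratio of GLI3 was -0.19 in ES2 and -0.04 in H4 on the log2 scale, HHIP was 1.18-fold lower in ES2, and SMO was 1.20-fold lower in H4. GAS1, a Hedgehog co-receptor, was at least 1.76-fold lower in H4, whereas GPR161 was at least 1.31-fold and KIF7 1.69-fold higher there. Over the list of Hedgehog pathway genes, 5 of the 8 measured in ES2 and 6 of the 9 measured in H4 were lower. The list medians of -0.13 in ES2 (4.05 percentile) and -0.25 in H4 (15.3 percentile) did not stand apart from random lists, though in ES2 the median of -0.19 over genes detected on both arrays did. The H4 median was -0.04 with genes detected on 1 array held at their bound.

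The list of GLI targets went both ways in H4. Of 18 measured genes, 10 were higher and 8 lower, with a median log2 ratio of 0.23 (98.3 percentile), 4 genes at least 2-fold higher and 2 at least 2-fold lower. Those at least 2-fold lower were SNAI2 (log2 ratio -1.12) and WNT5A (-1.10), of which SNAI2 was chosen after its value was seen. FST was 10.9-fold, the cyclin CCND1 6.95-fold and the transcription factor SOX9 3.36-fold higher in H4, whereas their log2 ratios in ES2 were -0.17, -0.03 and 0.01. The mitotic transcription factor FOXM1 was 1.65-fold lower in H4, and BCL2, the inhibitor of apoptosis, was 1.30-fold higher in H4 and 1.32-fold higher in ES2. CCND2 was 1.49-fold higher in H4. In ES2 the median was 0.03 over 16 genes (70.5 percentile) and no gene reached 2-fold. The H4 median did not stand apart from random lists without background correction (0.171), with an offset of 50 (0.174), with median scaling (0.187), on the authors' scale (0.128) or without the detection filter (0.0803).

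Autophagy genes were slightly higher in both lines. In ES2, 30 of 42 measured genes were higher and the median log2 ratio was 0.10 (99.7 percentile), with none at 2-fold. In H4, 27 of 39 were higher and the median was 0.20 (99.6 percentile), with 3 at least 2-fold higher: WIPI1, which binds early autophagosome membranes (2.60-fold), MAP1LC3B, the LC3 protein of the autophagosome membrane (2.48-fold), and the mitophagy receptor BNIP3 (2.38-fold). Their log2 ratios in ES2 were 0.10, 0.25 and 0.14. MAP1LC3A was 1.81-fold and the cargo receptor SQSTM1 1.46-fold higher in H4, against 1.14-fold and 1.18-fold in ES2. The initiating kinase ULK1 was 1.20-fold lower in H4 and 1.31-fold lower in ES2, BECN1 was 1.16-fold lower in H4 and 1.11-fold higher in ES2, and ATG2A was 1.56-fold higher in H4 and 1.48-fold lower in ES2. The BECN1 ratios were about the size of the spread between probes (SD of 0.222 in H4 and 0.143 in ES2). The H4 median did not stand apart at a detection p under 0.05 (0.144) or without the filter (0.112). Lysosomal genes were higher in H4, with 31 of 32 above 0, a median of 0.49 above all random lists and 5 genes at 2-fold, among them the cholesterol transporter NPC1 (2.53-fold), the GTPase RRAGD (2.43-fold) and the sialidase NEU1 (2.05-fold), while NPC2 was 1.75-fold higher. In ES2 the lysosomal median was 0.05 (89.6 percentile), with NEU1 at 1.61-fold and NPC2 at 1.40-fold higher.

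Mitotic genes gave the lowest list median in H4. All 40 of them were lower with GANT61 there, 32 of them at least 2-fold (31 with genes detected on 1 array at their bound), with a median of -1.48 below all random lists. Besides KIF20A and DLGAP5, the anaphase activator CDC20 was 3.94-fold and the kinesin KIF4A 3.45-fold lower. The same list had a median of -0.01 in ES2 (44.4 percentile), where KIF4A was 1.38-fold higher. Of the DNA replication genes, 35 of 36 were lower in H4, 9 at least 2-fold, with a median of -0.78 below all random lists, among them the transcription factor E2F2 (2.81-fold lower), the primase subunit PRIM1 (2.78-fold) and the polymerase subunit POLE2 (2.18-fold). This list also stood apart in ES2, where 24 of 35 were lower and the median was -0.18, below all random lists. The helicase subunit MCM5 was 1.48-fold lower in ES2 and 1.82-fold lower in H4. Histone genes had a median of -0.79 in H4, with all 13 lower and 6 at 2-fold, including H2AC6 (3.77-fold lower), H4C3 (3.55-fold), H2AX (2.03-fold) and H2BC12 (2.01-fold), against a median of 0.08 in ES2 (88.7 percentile). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 2.53-fold higher in H4 and 1.16-fold higher in ES2.

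**Figure D2:**
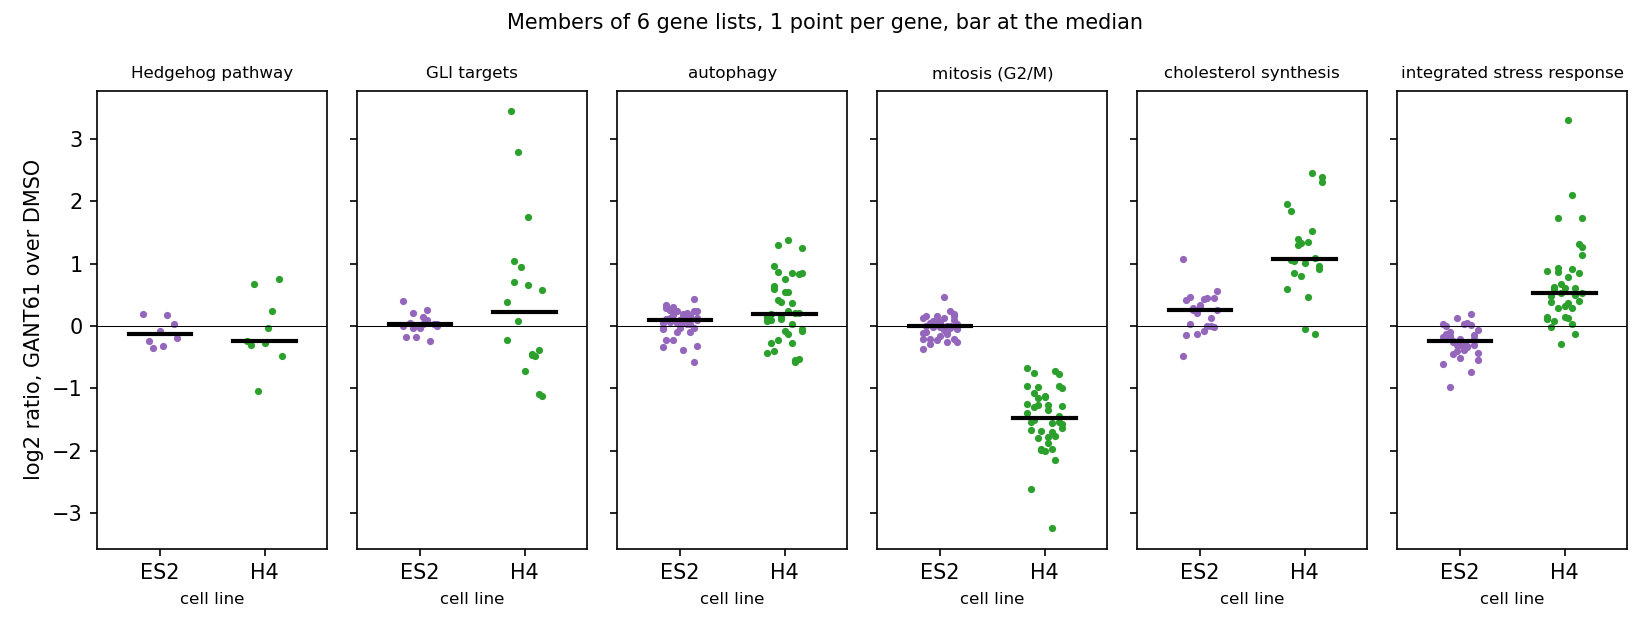
Log2 ratio of GANT61 over DMSO (y axis) of the measured members of 6 gene lists in ES2 and H4 (x axis), 1 point per gene with a black bar at the median. All 40 mitotic genes lie below 0 in H4 around a median of -1.48, and the integrated stress response list has a median of -0.23 in ES2 and 0.54 in H4.

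Genes of cholesterol synthesis were higher in both lines. In H4, 20 of 22 were higher, 14 of them at least 2-fold, and the median was 1.08 above all random lists. The last enzyme of the pathway, DHCR7, was 5.28-fold higher, the sterol oxidase MSMO1 4.97-fold and HMGCS1, which makes HMG-CoA, 3.58-fold. In ES2, 17 of 22 were higher and the median was 0.26, also above all random lists, with ACAT2 as the gene past 2-fold and HMGCS1 at 1.27-fold. Fatty acid synthesis genes had a median of 0.37 in H4 (99.6 percentile), with the desaturase SCD 3.40-fold, FASN 2.31-fold and ACSS2 2.23-fold higher, and of -0.09 in ES2 (5.99 percentile), where FASN was 1.22-fold lower. Hypoxia and glycolysis genes were all higher in H4, 33 of 33, with 14 at 2-fold and a median of 0.85 above all random lists, among them, besides CA9, the enolase ENO2 (8.05-fold), ALDOC (5.08-fold) and the peptide hormone ADM (3.77-fold). In ES2 the median was -0.03 (19.4 percentile). Oxidative phosphorylation genes were lower in H4, with a median of -0.24 over 41 genes (0.21 percentile) and none at 2-fold, as in UQCRB (1.76-fold lower) and ATP5MC1 (1.77-fold lower). In ES2 the median was 0.05 (94.9 percentile), UQCRB was 1.33-fold and ATP5MC1 1.25-fold higher, and NDUFV1 was lower in both lines, 1.42-fold in ES2 and 1.33-fold in H4.

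Of the stress lists, only the integrated stress response stood apart in both lines on opposite sides. Integrated stress response genes had a median of 0.54 in H4, above all random lists, with 36 of 39 higher and 7 at 2-fold, among them GDF15, the hormone STC2 (4.30-fold) and PPP1R15A (3.35-fold). In ES2, 27 of 33 were lower and the median was -0.23, below all random lists. DDIT3, the transcription factor CHOP, was 1.10-fold higher in H4 and 1.31-fold lower in ES2. Its H4 ratio (0.138 on the log2 scale) was smaller than the spread between probes there (SD of 0.222). In H4, p53 targets (median 0.58, above all random lists, 6 of 22 at 2-fold higher), heat shock genes (0.28, 99.4 percentile), apoptosis genes (0.22, 98.6 percentile) and ribosome biogenesis genes (0.18, 97.8 percentile) were higher, and NRF2 targets (-0.23, 2.32 percentile) were lower. NRF2 targets did not stand apart under 6 of the alternatives and apoptosis genes under 3. Examples were the death receptor TNFRSF10B (2.67-fold higher), the TNF receptor TNFRSF1A (2.21-fold lower), the chaperones HSPB8 (2.53-fold higher) and DNAJB1 (2.17-fold higher), RRP12 (1.75-fold higher), and the reductases AKR1C3 (4.10-fold lower) and NQO1 (2.07-fold lower). The same lists did not stand apart in ES2, with medians of 0.07 for p53 targets (93.2 percentile), -0.02 for heat shock (29.7), -0.07 for apoptosis (5.54), -0.06 for ribosome biogenesis (8.72) and 0.01 for NRF2 targets (61.6). Metallothioneins, which bind zinc and copper, stood apart in both lines, though not under 1 alternative in each. The H4 median was 1.41 over 5 genes (MT1X 3.71-fold, MT1G 3.13-fold and MT1A 2.66-fold higher). The ES2 median was 0.16 over 8 genes (98.4 percentile, MT1X 1.29-fold). With the gene detected on 1 ES2 array at its bound, it was 0.10, inside the range of random lists (-0.14 to 0.14). Endoplasmic reticulum chaperones did not stand apart (0.14 in H4, 95.0 percentile, and 0.06 in ES2, 91.9 percentile), though the oxidase ERO1A was 2.89-fold higher in H4.

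Inflammatory genes of NF-kB had a median of 1.04 in H4 over 14 genes, above all random lists, with 7 at least 2-fold higher (6 with genes detected on 1 array at their bound) and 1 lower. The chemokine CXCL8 was 6.48-fold, the cytokine IL6 5.25-fold and the cyclooxygenase PTGS2 3.63-fold higher, and VCAM1 was the gene at least 2-fold lower. In ES2 the median was 0.08 (92.4 percentile). Matrix and TGF-beta genes went both ways in H4, 7 at least 2-fold higher and 4 lower, with a median of 0.06 (85.5 percentile). There CCN1 and CCN2 (8.11-fold) were higher and the collagen COL3A1 was at least 3.76-fold lower. In ES2 their median was 0.08 (97.1 percentile). Mesenchymal markers had a median of -0.93 in H4, below all random lists, with 6 of 12 at least 2-fold lower, among them the small calcium-binding protein S100A4 (3.54-fold), the matrix proteoglycan LUM (3.07-fold) and DCN (at least 2.37-fold). In ES2 their median was 0.23 over 9 genes (99.6 percentile), which did not stand apart under 2 of the alternatives. With genes detected on 1 array held at their bound, the medians were -0.67 in H4 and 0.09 in ES2. The remaining lists did not stand apart. In H4 their medians were 0.23 for WNT and Notch (95.2 percentile), with DKK1 higher, JAG1 2.62-fold higher and LEF1 3.70-fold lower, 0.01 for interferon (66.5), with PSMB9 3.33-fold and PSMB8 2.13-fold lower, -0.08 for ribosomal proteins (19.1), -0.32 for Müllerian and epithelial markers (7.94), -0.02 for glial and neural markers (68.3), with OLIG2 3.14-fold higher, and -0.18 for blood cell markers (34.8). In ES2 they were -0.03 for WNT and Notch (29.0), 0.08 for interferon (95.5), 0.02 for ribosomal proteins (72.2), -0.09 for Müllerian and epithelial markers (21.3) and 0.03 for glial and neural markers (61.0), and 1 blood cell marker was measured. In all, 13 lists were higher and 6 lower than random lists in H4 and 4 higher and 2 lower in ES2. Were genes independent, chance would put 1.40 lists outside in H4 and 1.35 in ES2. Genes of a list can move together and lists share genes, so a difference between 2 cultures can put more lists outside. With nothing changed and independent simulated noise, 5 of 55 list medians stood apart.

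**Figure D3:**
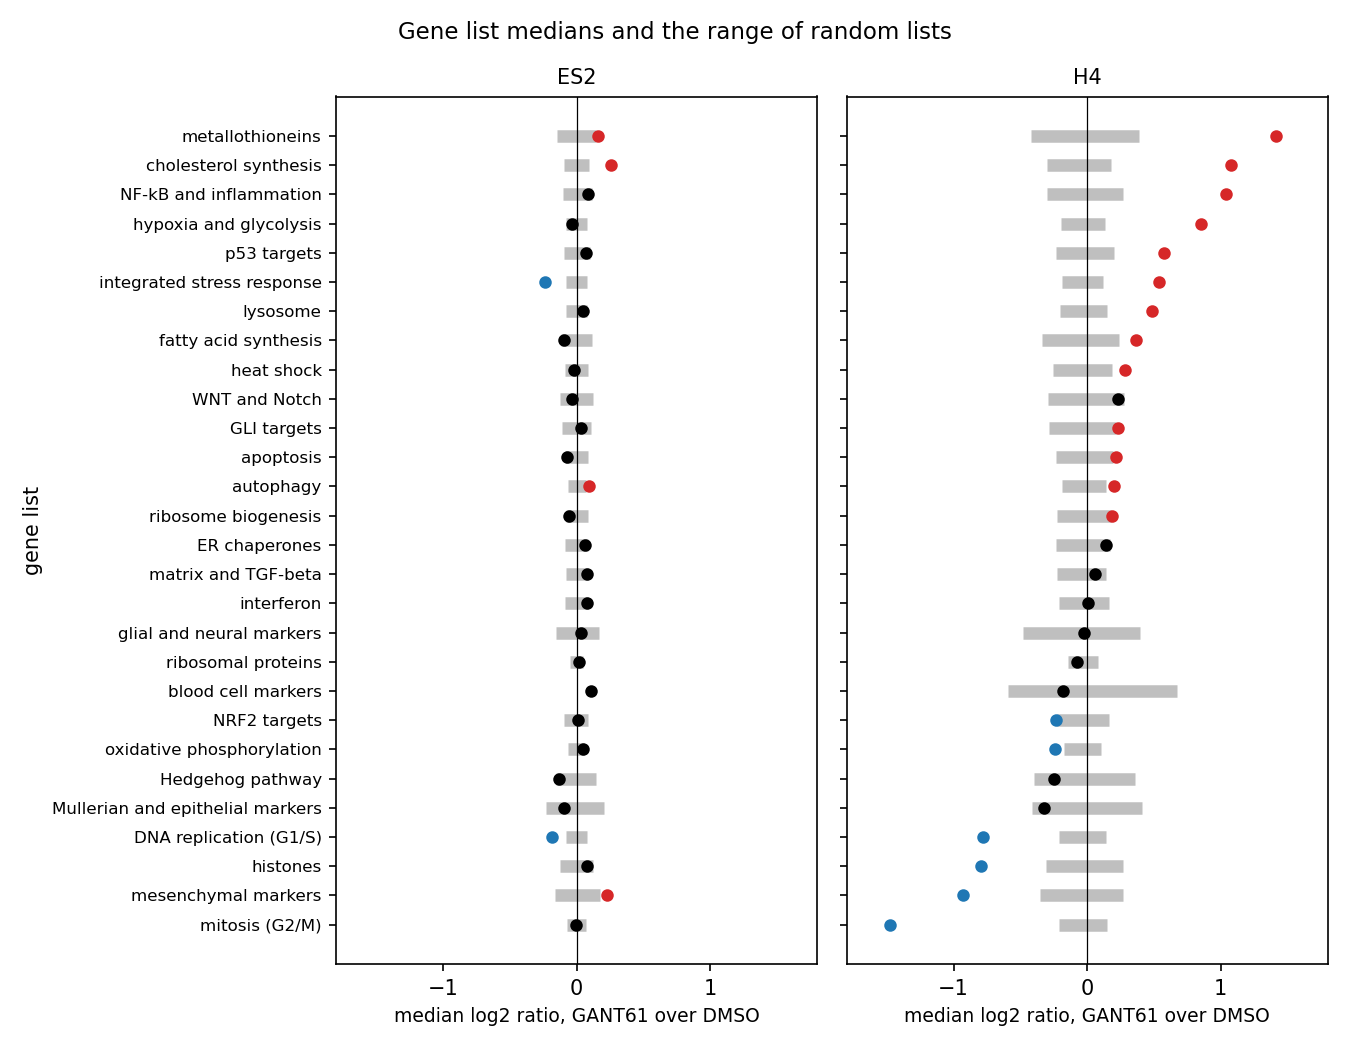
Median log2 ratio of GANT61 over DMSO (x axis) of 28 gene lists (y axis) in ES2 and in H4, with grey bars from the lowest to the highest 2.5% of 10000 random lists matched on signal. Red points lie above and blue points below that range. In H4, 13 lists lie above and 6 below it, and in ES2 4 and 2.

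The response shared by the lines was tested with the lines as the 2 replicates. Limma called 16 of 10229 genes, 14 higher and 2 lower with GANT61. Genes that rose included IL24 (log2 ratio 2.04 ± 0.33 SE, adjusted p = 0.00904), ALDOC (1.64 ± 0.30, adjusted p = 0.0160), GPNMB (1.88 ± 0.35, adjusted p = 0.0160), PSG4 (2.27 ± 0.42, adjusted p = 0.0160) and RNY4 (2.03 ± 0.38, adjusted p = 0.0160). Of the 16, 7 were detected on 1 H4 array (RNY4, RNY1, KRT34, PSG3, PSG5, TM4SF19 and VCAM1), so their ratios and p rest on an undetected array, and limma called 0 genes among those detected on all 4 arrays when tested alone (457 at an unadjusted p under 0.05). Those that fell were KIF20A (-1.75 ± 0.38, adjusted p = 0.0474) and VCAM1 (-1.84 ± 0.40, adjusted p = 0.0474). CXCL8 and RNA5S9 also rose. The other 7 that rose, PSG3, PSG5, TM4SF19, KRT34, RNY1, MIR1974 and MIR1978, fall outside the rule for named genes and were named after their values were seen. The unadjusted p was under 0.05 for 624 genes, against 511 by chance. These calls came largely from H4, where the ratio was over 3 times that in ES2 for 14 of the 16, and they rest on a shrunken spread: the median residual SD of the called genes was 1.19 before shrinkage and 0.332 after. No gene was called by limma under most of the alternatives, among them robust shrinkage (390 genes at an unadjusted p under 0.05), shrinkage without a trend (576) and no cell line block (20). In ES2 a second detected probe of IL24 had a log2 ratio of -0.05, against 0.84 for the probe used. The VCAM1 probe detected on all 4 arrays had 0.03 in ES2 and -0.37 in H4, against -0.17 and -3.50 for the probe used, which was detected on 1 H4 array.

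Over each list alone, limma called more genes. Of 20 cholesterol synthesis genes, 14 rose when adjusted over the list alone and none over all genes, and of 40 mitotic genes, 23 fell when adjusted over the list alone and 1 over all genes. These calls too came largely from H4: of the 23 mitotic genes, 15 were lower and 7 higher in ES2, whereas of the 14 cholesterol genes 12 were higher and 2 lower there. The corresponding counts over the list alone were 7 of 32 for hypoxia and glycolysis, 6 of 26 for matrix and TGF-beta, 4 of 14 for GLI targets, 4 of 5 for metallothioneins and 1 of 14 for fatty acid synthesis, all higher. They were 3 higher and 1 lower of 11 for NF-kB, 1 higher and 1 lower of 11 for WNT and Notch and 1 lower of 9 for histones. The GLI targets called were CCND1, CD44, FST and SOX9. In ES2 the sign was the other way for 3 of the 6 matrix genes and 2 of the 4 GLI targets. So it was for 1 of the 4 NF-kB genes, the 2 WNT and Notch genes and the histone gene. For the hypoxia, metallothionein and fatty acid synthesis genes called, the sign was the same in both lines. Within the Hedgehog, autophagy and lysosome lists, no gene was called either way. BNIP3, which the autophagy list shares with the hypoxia and glycolysis list, was called over the latter alone. Against the other genes, camera with a preset correlation called 17 of 27 lists. Cholesterol synthesis (adjusted p = 1.19e-19), hypoxia and glycolysis (1.44e-14), metallothioneins (5.49e-09), lysosome (6.16e-08), matrix and TGF-beta (0.000157), p53 targets (0.000253), GLI targets (0.00125), autophagy (0.00186), integrated stress response (0.00199), NF-kB (0.00295), fatty acid synthesis (0.00821), heat shock (0.0340) and chaperones (0.0422) were higher, and mitosis (1.30e-32), DNA replication (2.86e-12), histones (0.0112) and oxidative phosphorylation (0.0422) lower. A call over both lines does not show that both lines moved, since in ES2 the medians of the integrated stress response (-0.23), fatty acid synthesis (-0.09), heat shock (-0.02) and hypoxia (-0.03) lists, called higher, were below 0, and those of the histones (0.08) and oxidative phosphorylation (0.05), called lower, were above 0. No call held with an estimated correlation, where every list had an adjusted p = 0.665 or higher and camera gave 0 lists at an unadjusted p under 0.05. That estimate comes from 1 residual degree of freedom. On ranks, camera no longer called GLI targets (adjusted p = 0.0646), histones (0.0519) or chaperones (0.0827). The Hedgehog list was not called (adjusted p = 0.524 by camera), and its mean over the 6 genes detected in both lines was 0.07, of the other sign to its medians within each line. The median of the interferon list over both lines was 0.07 and its mean -0.02.

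Across the 10229 genes, which are not independent replicates, the ratios of the lines were not related (Pearson r = -0.01, Spearman rho = -0.05). At 2-fold, 2 genes were higher in both lines, MMP3 and RNA5S9, against 0.119 for independent lists, and 1 was lower in both, EGR1, against 0.0321. No gene was 2-fold different the same way in both lines without background correction or on the authors' scale, and 1 was with an offset of 50. At 1.5-fold, 11 were higher in both against 2.59 and 4 lower in both against 2.88. MMP3 was 2.18-fold higher in ES2 and 2.07-fold in H4, RNA5S9 2.01-fold and 3.33-fold, and EGR1 2.07-fold and 2.23-fold lower. The genes next highest in both were ALDOC, IL24, NEU1, LOC729222, PPFIBP1 (1.58-fold and 1.97-fold) and MAP3K7CL (1.54-fold and 3.79-fold). The genes next lowest in both were LAMA5 (1.68-fold and 1.70-fold), the DNA polymerase POLD1 (1.51-fold and 1.81-fold), MCM5, HOXB8, LUC7L, NRGN and the splicing factor SF3B3 (1.46-fold and 1.41-fold). Of the genes in this paragraph, RNA5S9, ALDOC and IL24 passed the shared test and the others did not, with adjusted p from 0.0649 (MAP3K7CL) to 0.852 (SF3B3) by limma, among them MMP3 (0.0706) and EGR1 (0.0960).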

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

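The tests of the quantile step, of a trend with signal level and of second probes were chosen after the results they bear on had been seen, and the other tests of this part before. The next results are ones where ES2 and H4 went opposite ways with GANT61, and after them come a difference in the number of genes and a group of small RNAs. No difference between the lines was tested, since each line had 1 array per treatment.

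SLC7A5, the large neutral amino acid transporter, had a log2 ratio of -0.97 in ES2 and 0.89 in H4, a difference of 1.86. PPP1R15A, the stress-induced partner of the eIF2α phosphatase, had -0.74 and 1.74, a difference of 2.48. GADD45A, a growth arrest gene, had -0.64 and 1.08, a difference of 1.73. SDHC, a subunit of succinate dehydrogenase, had 0.63 in ES2 and -0.62 in H4, a difference of -1.25. The median of the mesenchymal markers was 0.23 in ES2 and -0.93 in H4, a difference of -1.16. With genes detected on 1 array held at their bound, the medians were 0.09 in ES2 and -0.67 in H4. The former lay inside the range of random lists (-0.16 to 0.17). No explanation of the difference was tested.

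Integrated stress response genes had a median of -0.23 in ES2 and 0.54 in H4, a difference of 0.772. A trend of the ratios with signal level was argued against, because the ES2 median lay at the 0 percentile of random lists matched on signal and the H4 median above all of them. Disagreement between probes was also argued against, because the second brightest probe had a median of -0.209 in ES2 over 7 genes and 0.51 in H4 over 9, while genes with 1 probe could not be tested this way. A different stress response of the lines stays open, as do culture conditions such as nutrients or density, which 1 culture per treatment cannot separate from the compound.

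Many more genes differed by at least 2-fold in H4 than in ES2, 875 against 9. Noise of single probes in H4 was argued against. The ratios of the 2 brightest probes of a gene correlated across genes with Pearson r = 0.830 there. Both probes read the same labelled RNA on the same arrays. An error of the RNA, its labelling or a whole array would move both, so it stays open. The quantile step over 4 arrays was argued against as the whole cause, because 437 genes differed in H4 on the authors' scale, against 4 in ES2. An ES2 array from cells that did not receive the compound cannot be told apart from a line that responds little: of 558 genes at least 2-fold different in H4 and detected on all 4 arrays, 276 (49.5%) went the same way in ES2, which both would give, and although 11 genes were at least 1.5-fold higher in both lines against 2.59 by chance and cholesterol synthesis genes lay above all random lists in both, a difference between 2 cultures may give such values too. A lower sensitivity of ES2 to GANT61 and a chance difference between single cultures stay open as well.

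Small structured RNAs made up 5 of the 14 genes that rose in the shared fit, namely RNY1, RNY4, RNA5S9, MIR1974 and MIR1978. A rise of the whole class alike (which as listed also holds 18S and 28S ribosomal RNA) was argued against by its other members. Their median lay at the 48.6 percentile of random lists in ES2 and at the 8.32 percentile in H4. Small nucleolar RNAs were 86 of the 109 other members measured in ES2 and 59 of the 78 in H4. They largely set these medians, with a median of -0.13 in H4 (5.54 percentile). The log2 ratio of 28S was 2.27 in H4 and 0.07 in ES2, and that of 18S was 0.84 and -0.26. Without 18S and 28S, 76 other members were measured in H4 (8.33 percentile). Of these, 7 were at least 2-fold higher, among them RN7SK (log2 ratio 1.48) and RNU4-2 (1.39), and 1 was at least 2-fold lower. At any size of ratio, 31 were higher and 45 lower. A rise of part of the class, and with it another makeup of the labelled RNA, thus stays open. A change of RNA polymerase III output in both lines was not borne out, because the other polymerase III transcripts lay at the 86.8 percentile in ES2, though at the 99.8 percentile in H4 with a median of 0.52 over 8 transcripts. Signal from other sequences on the probes of these short RNAs was not tested and stays open.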

How the results depend on the processing

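Every alternative reported in this part was chosen before the data were examined. Across all of them, 477 list medians kept their side of the range of random lists, 20 no longer stood apart and 7 newly stood apart. In H4, NRF2 targets no longer stood apart under 6 alternatives, GLI targets under 5, apoptosis under 3, autophagy under 2 and metallothioneins under 1, and in ES2 mesenchymal markers under 2 and metallothioneins under 1. Matrix and TGF-beta genes in ES2 newly stood apart under 2, and under 1 each did Hedgehog, apoptosis and Müllerian markers in ES2 and WNT and Notch and Müllerian markers in H4. Of the named genes' log2 ratios, 1217 moved by less than the spread between probes and 198 by more, and none with a ratio of at least 2-fold changed sign. Over the scaling alternatives, the sign of DLGAP5 in ES2 changed, from -0.000879 to 0.000904 with median scaling.

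Without background correction, 1 ES2 gene was at least 2-fold higher and 1 lower, 240 H4 genes were lower, the H4 median of GLI targets was 0.171, limma called 8 genes higher and 0 lower over both lines (602 at an unadjusted p under 0.05), all 8 among the 16 called above, and 0 genes were 2-fold different the same way in both lines. With an offset of 50, the ES2 counts were 1 and 1, the H4 count lower was 248, the GLI target median 0.174, the limma calls 0 higher and 0 lower (562 unadjusted), and 1 gene was shared. With median scaling and no quantile step, the GLI target median was 0.187 and the limma calls 0 and 0 (456 unadjusted). On the authors' scale, the ES2 counts were 2 and 2, the H4 counts 256 and 181, the GLI target median 0.128, the limma calls 0 and 0 (459 unadjusted), and 0 genes were shared. The cause of these moves was not tested.

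With the mean of the detected probes, limma called 0 genes higher and 0 lower (585 unadjusted). At a detection p under 0.05, the H4 autophagy median was 0.144, no longer apart from random lists, and limma called 12 genes higher and 0 lower (671 unadjusted), 10 of them among the 16. With genes detected on all arrays of the comparison, fewer genes were tested. The ES2 counts were then 3 and 2, the ES2 Hedgehog median was -0.194 and stood apart, and limma called 0 and 0 of 8816 genes (457 unadjusted). With no filter on detection, the ES2 counts were 52 and 42, the H4 medians were 0.0803 for GLI targets and 0.112 for autophagy, neither apart, and limma called 0 and 0 of 30562 genes (1582 unadjusted). At a 1.5-fold threshold, the counts were 42 and 37 in ES2 and 1302 and 1446 in H4, and 15 genes were shared. Here the wider threshold is the cause.

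Limma called 0 genes higher and 0 lower without the cell line block (20 unadjusted), 0 and 0 without a trend (576 unadjusted) and 0 and 0 with robust shrinkage (390 unadjusted), so the calls depend on how the spread is shrunk. Camera called 17 lists with the preset correlation, 0 with an estimated correlation (0 unadjusted, smallest adjusted p = 0.665) and 14 on ranks, all 14 among the 17. Those lost on ranks were GLI targets, histones and chaperones. Without background correction and with median scaling, camera called the same 17 lists. Leaving out either line leaves no residual degree of freedom, so it gives the other line's ratios as values and no test. Signal over background limited what could be seen of the Hedgehog pathway, since PTCH1 and SUFU were detected on no array and 8 of 21 listed genes were measured in ES2 and 9 in H4.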

Other observations

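No test in this part was chosen after its result was seen, though the lists of ERK feedback genes and of YAP and TEAD targets were written after some of their members had been seen in H4. They were tested on the members recorded as not seen by then. Among these, MYC, LIF and TGFB2 also belong to the lists fixed earlier. DUSP6, SPRY1 and ANKRD1 are also among the genes with the largest H4 bounds (at least 4.68-fold, 4.93-fold and 5.61-fold higher). Unseen members were read on the same arrays as the seen ones, so this is not an independent test. Genes known as feedback inhibitors or early targets of ERK signalling were higher with GANT61 in H4, where the median log2 ratio of 15 such members was 1.51, at the 100 percentile of random lists matched on signal, and 11 of the 15 were at least 2-fold higher. Of the 15, 7 were detected on 1 H4 array, and with these at their bound the median was 1.27 and the count 10. Among them were the ERK phosphatase DUSP5 (log2 ratio 2.18) and the transcription factor ETV5 (1.68), both detected on both H4 arrays, while EPHA4 was lower (-0.71). EGR1, itself an ERK target, was lower in both lines, so the pattern is not uniform. A hypothesis is a higher ERK output in H4 at 48 h. Phosphorylated ERK was not analysed here, and cell density could change the same genes. In ES2 the median of 16 such members was -0.15, at the 0.58 percentile, and the difference between the lines was not tested.

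Targets of YAP and TEAD, transcription factors that respond to cell shape and density, were also higher in H4. The median of the 14 members not seen beforehand was 0.99, at the 100 percentile, with 7 of the 14 at least 2-fold higher, among them the small GTPase RND3 (log2 ratio 2.37) and the membrane protein MYOF (1.54). IGFBP3 was lower (-1.16). In ES2 the median of 18 members was 0.03, at the 71.9 percentile. A changed YAP and TEAD output in H4 is a hypothesis that this test on unseen members left standing and did not decide, since 1 culture per treatment cannot separate the compound from cell density, and the location of YAP in the cells was not analysed here. DUSP5, ETV5, EPHA4, RND3, MYOF and IGFBP3 were chosen after their values were seen.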
